A study of Mus musculus with 5 samples.

How the data were processed

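RNA of mouse bone marrow-derived macrophages was compared with a common reference on 5 two-colour cDNA arrays. The macrophages came from C3H/ARC mice and had been differentiated in culture with CSF-1, the growth factor of this lineage. They were left untreated (0 h) or exposed to lipopolysaccharide (LPS), a component of the bacterial outer membrane, at 10 µg per ml for 0.5, 2, 7 or 21 h. Channel 2 of every array held RNA of whole C57BL6/J embryos at day 17.5. Each time point was measured on 1 array, so there are no replicates, no p-value is given, and the number of arrays limits the precision of every value.

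The deposited values are log ratios per probe, which were read as log10. The labels state neither the log base, nor the direction of the ratio, nor which dye each channel carried, and the normalization by the authors is not given in the sources used here. Base 10 was inferred from the values. On the 0 h array they ran from -0.378 at the 5th percentile to 0.415 at the 95th, which on a log2 scale would be small ratios between macrophages and whole embryo. If the base was 2, every log2 change below is 3.32 times too large, while with all probes the order of the genes, the percentiles of lists and the correlations stay as given. Other runs would then be marked, so values without the affected runs would differ. The direction, macrophage over embryo, is likely and rests on marker lists fixed before the data were examined. On the 5 arrays the median deposited value of 17 macrophage identity markers was 0.556, 0.391, 0.446, 0.374 and 0.305 in order of time. That of 36 whole-embryo markers was -0.322, -0.472, -0.378, -0.508 and -0.460, and the median of all probes was 0.041, 0.029, 0.050, -0.024 and -0.0018. If the direction was the other one, higher and lower would exchange throughout.

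Of 19828 probes, 14759 carried exactly 1 gene symbol in the platform annotation of 2008, 170 carried several, and 4899 were not listed there and are unnamed here. Entrez identifiers matched 14628 of the probes with 1 symbol to the gene table of assembly GRCm38.p6, and the others kept their annotated symbol. Values were multiplied by 3.32 to give log2 ratios, and each array was centred on its median over the 18296 probes measured on all 5 arrays. Named probes measured on all 5 arrays (13782) were averaged per symbol, giving 8637 genes, of which 3015 had 2 or more probes. The change of a gene is its log2 ratio at a time minus that at 0 h. Genes at or beyond 2-fold were counted as a rule of size. The SD over probes of one gene, pooled over the genes with several probes, was 0.67, 0.97, 0.51 and 0.47 on the log2 scale at 0.5, 2, 7 and 21 h. It is technical and includes differences between clones, and a value given with "SD over probes" below uses this spread within one gene.

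The genes named in the text follow a rule fixed before the data were examined. For 2, 7 and 21 h these are the 8 highest and 8 lowest genes, ranked by the smaller of the changes from 0 h and from 0.5 h, that also differed from 0 h by at least 1.5-fold in the same direction at another of these times. For 0.5 h they are the 8 highest and 8 lowest by change from 0 h that differed by at least 1.5-fold in the same direction at 2 h. Up to 4 members with the largest change were added from each fixed list described, as well as 18 genes of the LPS response, of which 7 were measured. Where another gene is named, the text says so.

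The 24 gene lists, fixed beforehand, cover immediate early genes, cytokines, chemokines, the NF-kappaB pathway, endotoxin signalling, interferon response, antigen presentation, effectors, lysosome, cell cycle, sterol synthesis, oxidative phosphorylation, glycolysis, heat shock, ribosomal proteins, and markers of macrophages, neutrophils, B cells, T and NK cells, dendritic cells, mast cells, erythroid cells, stroma and whole embryo. The median change of each list was set against 10000 random lists of the same size, matched in 20 bins of the mean ratio over the 5 arrays. Its percentile among them describes these arrays and is no test across animals. A list is called high or low where its median lies outside the middle 95% of its random lists.

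Probe numbers were divided into 207 runs of 96 consecutive numbers. After seeing the data, the 94 runs in which at least 10% of probes lay 2-fold or more above 0 h at 0.5 h or 2 h were marked as affected, and every count and list was computed again without them (5996 genes). Leaving out runs picked for high early values in itself lowers the early counts and list medians. The mean ratio used to match random lists includes the 0.5 h and 2 h values. With all probes, random lists for high-ratio lists therefore take in high early values of these runs. Early percentiles of such lists with all probes can be too low for this reason. The comparisons of times share the 0 h array. Their counts, correlations and overlaps are therefore set beside those of simulated unchanged arrays with the spread between probes at 21 h, and for pairs of later times also computed with 0 h as baseline for one time and 0.5 h for the other. The simulation holds no other difference between arrays. With all probes the spread was larger at 0.5, 2 and 7 h than at 21 h. Without the runs it was 0.42, 0.55, 0.50 and 0.43 at 0.5, 2, 7 and 21 h. Simulated counts are therefore no exact no-change values for the times before 21 h. Other settings tried were values without centring, quantile normalization, limits of 1.5-fold and 3-fold, single probes, a filter on low ratios, other baselines, means of lists, quantile normalization of only the probes outside the runs, and random lists that were not matched.

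The steps were tested on simulated data made for 7 h against 0 h over 8637 genes. The 2-fold limit recovered 92% of genes changed by 1.5 on the log2 scale and 100% of those changed by 2.5, of 200 changed genes in all, and called 2.75% of unchanged genes. All 20 runs made with high values were found, with 0 others. A list shifted by 0.8 had the percentile 100, and 5 of 96 unshifted combinations of list and time lay outside the middle 95%. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.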

Results

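The series followed the transcriptome of bone marrow-derived macrophages of C3H/ARC mice through 21 h of LPS, with 1 array each at 0, 0.5, 2, 7 and 21 h. The question was which genes differ from unstimulated cells at each time and which differ early or late. Of the 19828 probes, 19413, 19351, 19344, 19670 and 19649 had a value on the arrays in order of time. The 0.5 h and 2 h arrays held many more high ratios than the others. On them 2.86% and 4.35% of probes lay at least 10-fold above the array median, against 0.191%, 0.498% and 0.443% at 0, 7 and 21 h. Ratios at least 10-fold below the array median made up 0.917%, 1.15%, 1.10%, 1.01% and 0.870% in order of time. The high values at 0.5 h and 2 h followed the probe number. In the 94 affected runs, which hold 45.3% of probes, 16.4% of probes lay at least 2-fold above 0 h at 0.5 h and 27.4% at 2 h, but 5.72% at 7 h and 5.07% at 21 h. In the remaining runs the shares were 1.59%, 4.38%, 5.04% and 3.17%. The runs were picked by these early shares, which widens the contrast. With runs picked on odd-numbered probes alone, the shares of even-numbered probes were 15.9% inside and 1.73% outside at 0.5 h, and 25.6% and 4.62% at 2 h. Counts and lists at 0.5 h and 2 h are therefore given with and without the affected runs, while values of single genes use all their probes.

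**Figure D1:**
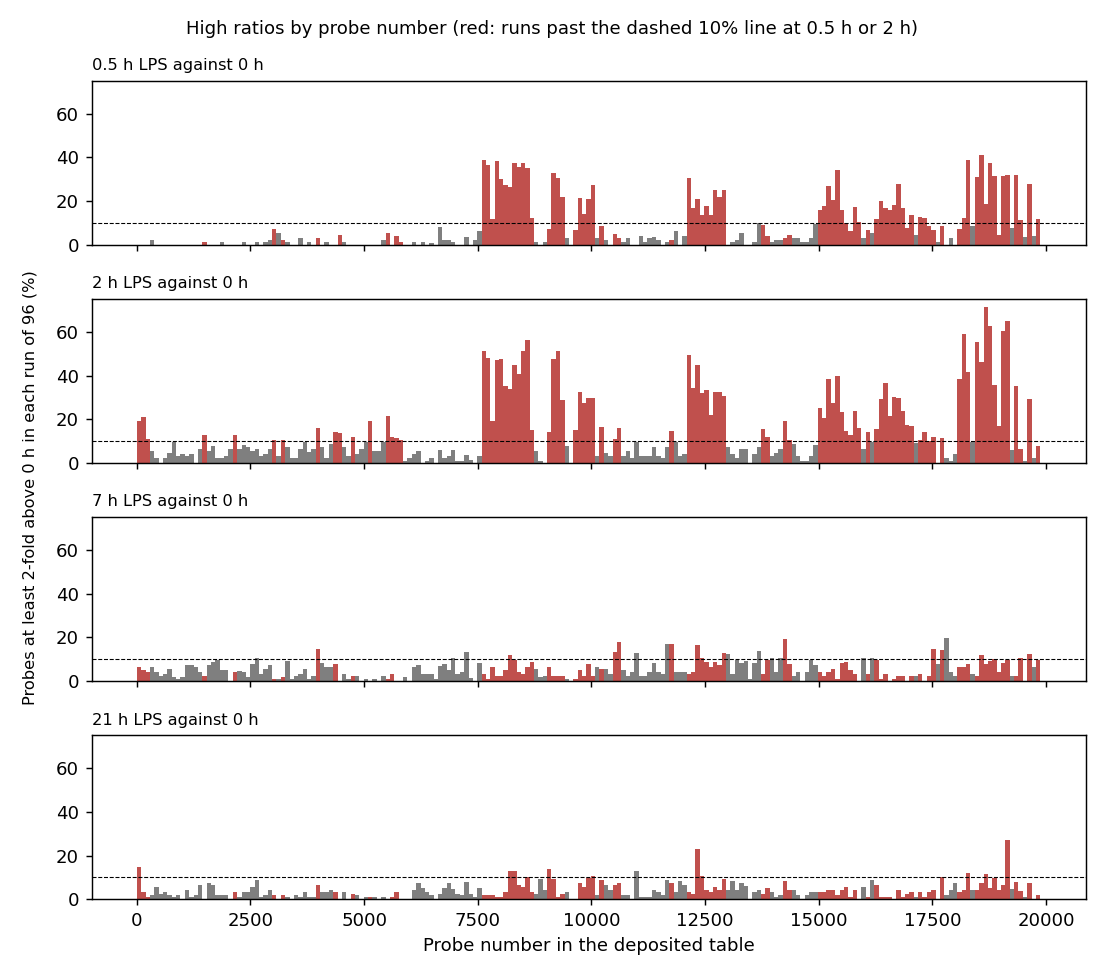
Percentage of probes at least 2-fold above the 0 h array (vertical axis) in each run of 96 consecutive probe numbers (horizontal axis), 1 panel per time of LPS. Red bars are the 94 affected runs, grey bars the other runs, and the dashed line is the 10% limit. The blocks of high bars at 0.5 h and 2 h are largely absent at 7 h and 21 h, although single runs within them stay above the limit.

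After 0.5 h, immediate early genes stood above the 0 h array. Fos, a subunit of the AP-1 transcription factor, was 4.98-fold higher, its partner Junb 3.78-fold, and the antiproliferative gene Btg2 3.46-fold (log2 change 1.79, SD over probes 0.13, 3 probes). The stress-response gene Ier3 was 2.67-fold higher. By 2 h Fos was back at 0.814 and Btg2 at 1.16 of the 0 h level. Of the 20 measured immediate early genes, 8 were at least 2-fold higher and 0 lower. The list median of 0.54 lay at percentile 99.1 of its random lists, but without the affected runs it was 0.16 at percentile 87.1, with 2 of 13 genes at least 2-fold higher. The single probes of Fos, Junb and Ier3 lie in those runs. Nfkbia, the inhibitor of NF-kappaB, was 2.55-fold higher on a probe outside the runs. The chemokine gene Cxcl10 was 2.46-fold higher and the interferon-response gene Ifit1 4.08-fold (log2 change 2.03, SD over probes 0.77), both on probes in affected runs; under quantile normalization Ifit1 stood at -0.11.

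In all, 514 genes were at least 2-fold higher and 87 lower after 0.5 h, against 77 and 59 of 5996 genes without the affected runs, and 240 and 298 under quantile normalization. A simulated unchanged array gave 103 and 105, and 58 and 43 without the runs, so the lower genes number no more than in the simulation with all probes. The simulation uses the spread between probes at 21 h, 0.47 against 0.67 at 0.5 h with all probes, so it gives no exact count for an unchanged 0.5 h array. The 8 highest genes under the naming rule had log2 changes of 8.53 (Plut), 8.09 (Pdzph1), 7.17 (Kcne1), 6.83 (Fcgr1), 6.17 (AV064505), 6.15 (Pgs1), 6.11 (Lama1) and 5.99 (Rcbtb2), and each of them was measured only by a probe in an affected run. Fcgr1, the high-affinity IgG receptor of macrophages, had a change of 6.84 at 2 h and 1.52 at 7 h. The 8 lowest were Stfa3 (-6.12), Prl8a1 (-5.48), Klhdc3 (-3.10), Spock1 (-2.81), Mxi1 (-2.59, SD over probes 3.52), Serpinf1 (-2.48), Col22a1 (-2.44) and Fstl1 (-1.83). The first 5 of these were also more than 2 log2 units below 0 h at 2, 7 and 21 h, and the 2 probes of Mxi1 disagreed. For Stfa3 the later changes were -5.31, -5.38 and -5.41. All these changes share the 0 h array, so a high reading on that array alone would give the same pattern. The naming rule for 0.5 h does not guard against it.

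After 2 h, single cytokine and chemokine genes lay far above 0 h, while neither list did as a whole. The cytokine median of 0.90 lay at percentile 89.0 (3 of 6 genes at least 2-fold higher) and the chemokine median of 0.41 at percentile 83.0 (4 of 12). Outside the affected runs the chemokine median was 0.21 at percentile 90.4, with 0 of 8 genes at least 2-fold higher. Il1a, encoding the inflammatory cytokine interleukin 1 alpha, was 12.1-fold higher, Csf1, the growth factor of the lineage, 14.8-fold, and Cxcl10 14.0-fold. The chemokine genes Ccl9 and Ccl12 were 3.75-fold and 3.47-fold higher. All of these were measured by single probes in affected runs, and under quantile normalization Ccl9 stood at -1.10. Outside the runs, the antiapoptotic gene Bcl2a1a was 2.63-fold, the TNF receptor gene Tnfrsf1b 2.45-fold and Nfkbia 1.73-fold higher. The NF-kappaB list outside the runs had a median of 0.78 at percentile 99.2 (2 of 8 genes at least 2-fold higher). The endotoxin receptor and signalling list had a median of 0.43 at percentile 98.9 (0 of 6 genes at least 2-fold higher, 4 above 0). With all probes, the same lists lay at percentiles 66.0 and 90.4. In the second list the MAP kinase kinase kinase gene Map3k8 was 20.4-fold and the receptor gene Tlr2 2.57-fold higher, both on probes in affected runs and so not among those 6 genes.

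Of 30 interferon-response genes, 13 were at least 2-fold higher at 2 h and 0 lower. Ifit1 was 23.2-fold higher (log2 change 4.54, SD over probes 0.91), the antiviral gene Rsad2 10.7-fold (3.42, SD 1.28) and the kinase gene Eif2ak2 10.3-fold (3.36, SD 0.42). Both probes of Ifit1 and of Rsad2, and 1 of the 2 of Eif2ak2, lie in affected runs, and outside the runs 6 of 18 genes of the list were at least 2-fold higher. The list median of 0.82 lay at percentile 17.8, and without the affected runs it was 0.63 at percentile 95.9, in both cases inside the middle 95%. That range ran from 0.48 to 2.04 with all probes, where matching takes in high values of the runs, and from -0.13 to 0.70 without them. Under quantile normalization the median was -0.63 and the change of Rsad2 -0.70. That scaling is itself touched by the runs, whose probes took 90.3% of the highest 5% of ranks at 2 h and 86.9% at 0.5 h, against 58.3% at 0 h. Over the probes outside the runs it gave the list a median of 0.13 at percentile 89.1. Gadd45b, a stress-response gene of the immediate early list, was 7.41-fold higher (2.89, SD 0.67), and the cyclooxygenase gene Ptgs2 had a log2 change of -0.46.

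In all, 1071 genes were at least 2-fold higher and 95 lower at 2 h, against 253 and 93 without the affected runs, and 430 and 395 under quantile normalization. The simulated array gave 93 and 96 (48 and 47 without the runs). The lower genes thus number about as many as simulated with all probes, and more without the runs. The simulation uses the spread between probes at 21 h, 0.47 against 0.97 at 2 h, and 0.43 against 0.55 without the runs. It therefore gives no count for an unchanged 2 h array, and the excess without the runs may reflect that spread. The 8 highest genes under the rule were Fbxo31 (log2 change 8.91), Phactr3 (6.47), Edn2 (6.0), Bcl2l15 (5.70), Ctsq (3.98), Rab11fip1 (3.91), Csf1 (3.89) and Gsap (3.22), all measured only by probes in affected runs. The 8 lowest were Ablim1 (-2.80), Ly6g2 (-2.35), Dcakd (-1.90), Nans (-1.60), the replication gene Gins1 (-1.33), Zfp354b (-1.30), Chtf8 (-1.25) and Cyp2c65 (-1.24), of which 3 had their probe in an affected run.

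After 7 h, cytokine, NF-kappaB and interferon-response genes stood far above 0 h. Il1a was 36.9-fold higher, Cxcl10 42.8-fold and the interleukin 1 receptor antagonist gene Il1rn 7.99-fold. Ifit1 was 16.9-fold (log2 change 4.07, SD over probes 0.60), Rsad2 16.5-fold (4.04, SD 0.20) and Ifi204 10.9-fold higher. Complement factor B (Cfb) was 11.6-fold higher (3.54, SD 0.84) and Fgl2, a prothrombinase of activated macrophages, 9.0-fold (3.17, SD 0.50). Cyclin D1 (Ccnd1), which drives entry into the cell cycle, lay lower, with a log2 change of -2.29 (SD 0.97, 3 probes). All probes of Il1a, Cxcl10, Il1rn, Ifit1 and Rsad2 lie in affected runs. Those of Ifi204 and Fgl2 lie outside them, and Cfb and Ccnd1 have probes on both sides.

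The NF-kappaB list had 7 of 9 genes at least 2-fold higher and 0 lower at 7 h. Its median of 1.5 lay at percentile 100 of the random lists, and so did the median of 1.61 without the affected runs; against the 0.5 h array the median was 0.86. Birc3, an inhibitor of apoptosis, was 6.63-fold higher, Bcl2a1a 5.33-fold, Tnfrsf1b 4.80-fold and Nfkbia 3.31-fold, each on a probe outside the runs. Of 30 interferon-response genes 18 were at least 2-fold higher and 0 lower, with a median of 1.28, and 10 of 18 without the affected runs, with a median of 1.19, both at percentile 100. Among them the regulator Irf7 was 4.73-fold higher (2.24, SD 0.49) and Ifit2 7.64-fold. Of 6 inflammatory cytokine genes 4 were at least 2-fold higher, with a median of 1.31 at percentile 100; besides Il1a and Il1rn these were Csf1 (2.67-fold) and Il18 (2.30-fold). Only Il18 and Il15 of this list have probes outside the runs, too few for a list value there at any time. Of 12 chemokine genes 3 were at least 2-fold higher, namely Cxcl10, Ccl9 (5.03-fold) and Ccl12 (2.89-fold), with a median of 0.40 at percentile 98.8, against 0.35 at percentile 93.8 without the affected runs. The chemokine median also lay inside the middle 95% under quantile normalization and against the 0.5 h array. The list of antimicrobial, redox and acute-phase effectors had 7 of 25 genes higher and 1 lower, with a median of 0.30 at percentile 98.9 (87.1 without the runs), led by Cfb, the acute-phase gene Saa3 (6.82-fold), Serpinb2 (4.82-fold) and the superoxide dismutase Sod2 (4.57-fold, SD 1.87). Saa3, Serpinb2, Ifit2, Csf1, Ccl9 and Ccl12 were measured only by probes in affected runs.

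The cell cycle and DNA replication list had 7 of 55 genes at least 2-fold lower and 1 higher at 7 h. Its median of -0.25 lay at percentile 0.010, but without the affected runs it was -0.094 at percentile 10.1 (31 genes). Besides Ccnd1, the ribonucleotide reductase gene Rrm2 (-1.49) lay lower, whereas the cyclin D2 gene Ccnd2 lay 2.92-fold higher (1.55, SD 0.49, 6 probes). In all, 352 genes were at least 2-fold higher and 273 lower, against 271 and 172 without the affected runs. The simulated array gave 95 and 111 (48 and 46 without the runs). It uses the spread at 21 h, 0.47 against 0.51 at 7 h (0.43 against 0.50 without the runs). These are therefore no exact counts for an unchanged 7 h array. The balance depended on scaling and baseline, with 220 higher and 510 lower without centring, 417 and 516 under quantile normalization, and 235 and 709 against the 0.5 h array. The remaining genes of the rule were Myot (2.92) on the higher side and Sirpa (-3.46), Myh11 (-3.31), Pir (-2.63), Cyp2e1 (-2.62), Pdxk (-2.6), Ccdc32 (-2.16) and Dusp19 (-2.13) on the lower side. Sirpa, an inhibitory receptor of macrophages with 1 probe, had a change of 0.06 at 21 h. Of the 8 highest and 8 lowest genes of the rule, 5 and 4 had all their probes in affected runs. The single probe of Rrm2 also lies in an affected run.

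**Figure D2:**
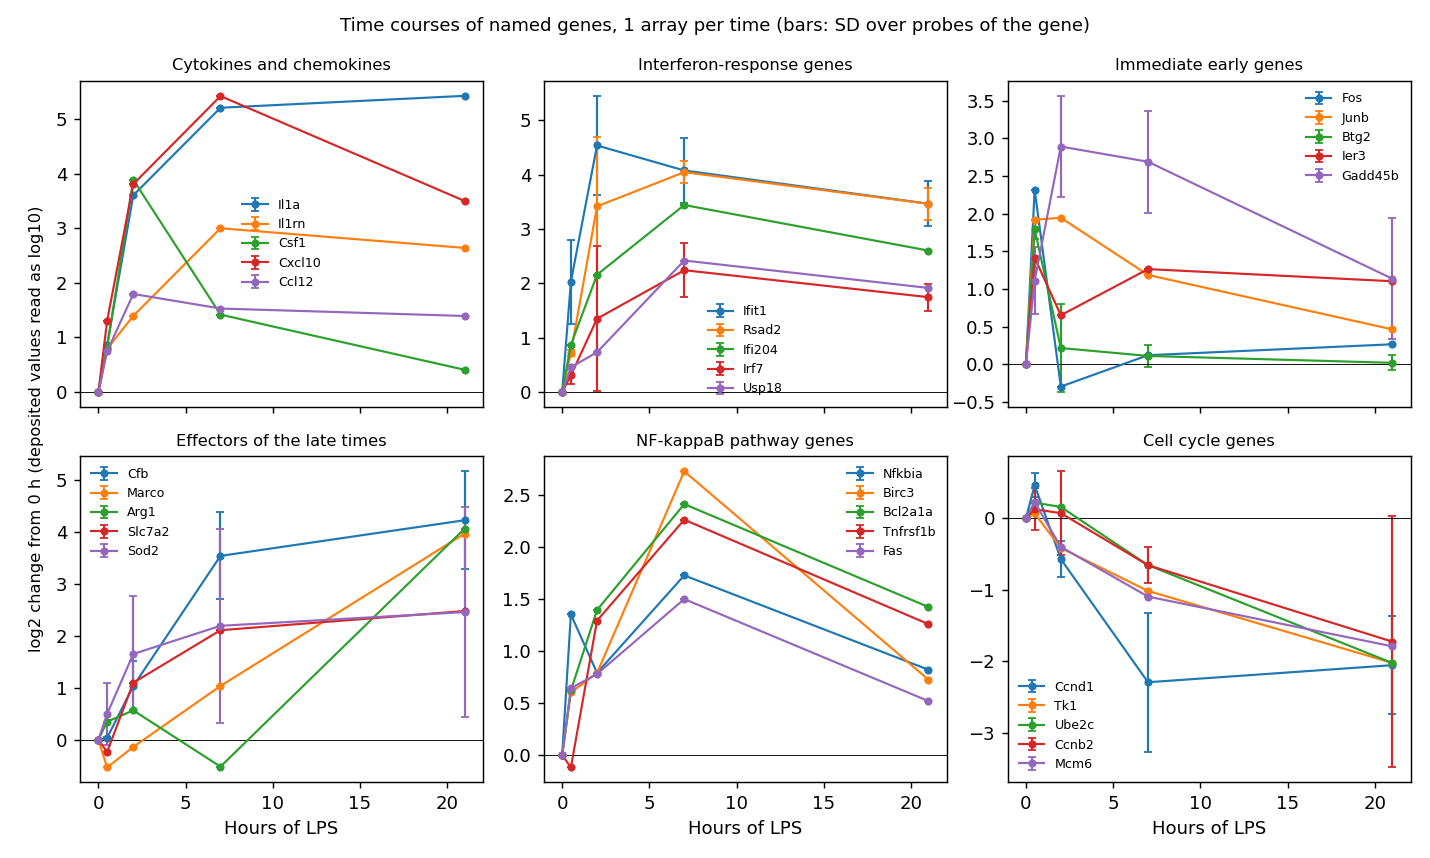
Change from the 0 h array on the log2 scale (vertical axis, deposited values read as log10) against hours of LPS (horizontal axis) for named genes in 6 groups, 1 array per time; bars are the SD over probes of a gene and are absent for genes with 1 probe. Fos and Btg2 peak at 0.5 h, Cxcl10 and Birc3 at 7 h, and Marco and Arg1 stand highest at 21 h.

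After 21 h, Il1a and several effector genes lay far above 0 h. Il1a was 42.9-fold and Cfb was 18.7-fold higher (log2 change 4.22, SD over probes 0.94). Arginase 1 (Arg1), which degrades arginine, was 16.7-fold higher after a change of -0.52 at 7 h, and the scavenger receptor gene Marco 15.6-fold after 2.05-fold at 7 h. Pla2g7, a phospholipase that degrades platelet-activating factor, was 12.3-fold higher and the plasminogen activator inhibitor gene Serpinb2 7.49-fold. Cell cycle genes lay lower, among them Ccnd1 (-2.06, SD 0.68), the ubiquitin-conjugating enzyme gene Ube2c (-2.02), thymidine kinase 1 (Tk1, -2.02) and the replication helicase gene Mcm6 (-1.79). The single probes of Ube2c, Tk1, Mcm6, Il1a, Arg1 and Serpinb2 lie in affected runs, and those of Marco and Pla2g7 outside them.

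The effector list had 11 of 25 genes at least 2-fold higher and 0 lower at 21 h, with a median of 0.31 at percentile 99.3 (93.3 without the affected runs). The interferon-response list had 11 of 30 higher and 0 lower, with a median of 0.79 at percentile 100 and 0.74 at percentile 99.9 without the runs. Ifit1 and Rsad2 were each 11-fold higher (SD 0.42 and 0.30), Ifit3 6.29-fold and Ifi204 6.07-fold. Ifit3, on a probe outside the runs, had log2 changes of 1.14 at 2 h and -0.18 at 7 h, unlike Ifit1 and Ifit2. The NF-kappaB list had a median of 0.73 at percentile 99.9, with 3 of 9 genes at least 2-fold higher, but against the 0.5 h array its median was 0.12 and inside the middle 95%. The cytokine list had a median of 0.48 at percentile 98.4, with Il1a and Il1rn (6.23-fold) at least 2-fold higher, but inside the middle 95% against the 0.5 h array. Glycolysis genes had a median of 0.53 at percentile 100, with 5 of 18 at least 2-fold higher and 0 lower, and 0.46 at percentile 100 without the runs. Pfkfb3, which makes an activator of glycolysis, was 3.87-fold higher, the hypoxia-inducible factor gene Hif1a 3.84-fold (1.94, SD 0.64, 6 probes), Bnip3 2.88-fold (1.52, SD 0.23) and Tpi1 2.27-fold (1.18, SD 0.25, 5 probes). Antigen presentation genes had a median of 0.40 at percentile 98.8 (81.5 without the runs, 89.0 under quantile normalization). Among them Tapbp was 2.51-fold and B2m 2.05-fold higher (1.03, SD 0.39). All 6 probes of Hif1a and the single probe of Tapbp lie in affected runs. That of Pfkfb3 lies outside them, and B2m has probes on both sides.

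The cell cycle list had 18 of 55 genes at least 2-fold lower and 0 higher at 21 h, with a median of -0.52 that lay below all 10000 random lists. Without the affected runs 6 of 31 were lower and 0 higher, with a median of -0.34, again below all of them. On the same array the median of the neutrophil and granule markers was -0.27 at percentile 1.9 (8 genes; -0.37 at percentile 2.86 without the runs), and inside the middle 95% against the 0.5 h array. In that list the granule genes Ngp (-1.62, SD 1.08) and Mpo (-1.25) were lower and the gelatinase gene Mmp9 3.62-fold higher. The ribosomal protein list had a median of -0.20 below all its random lists (64 genes; -0.13 at percentile 0.110 without the runs), with 1 gene at least 2-fold lower. The sterol synthesis list had a median of -0.18 at percentile 2.47 (14.7 without the runs). In all, 263 genes were at least 2-fold higher and 125 lower, against 153 and 65 without the affected runs. The simulated array gave 96 and 104 (48 and 49), close to the lower counts. Here too the balance depended on scaling and baseline, with 190 and 222 without centring, 324 and 391 under quantile normalization, and 195 and 627 against the 0.5 h array. The remaining genes of the rule were Fgl2 (2.89, SD 0.37) and Myot (2.5) on the higher side and the transferrin receptor gene Tfrc (-2.09), the kinetochore gene Knl1 (-1.84), Myh11 (-1.82), Cdca5 (-1.80) and Ccdc32 (-1.79) on the lower side. Of the 8 highest and 8 lowest genes of the rule, 4 and 6 had all their probes in affected runs.

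**Figure D3:**
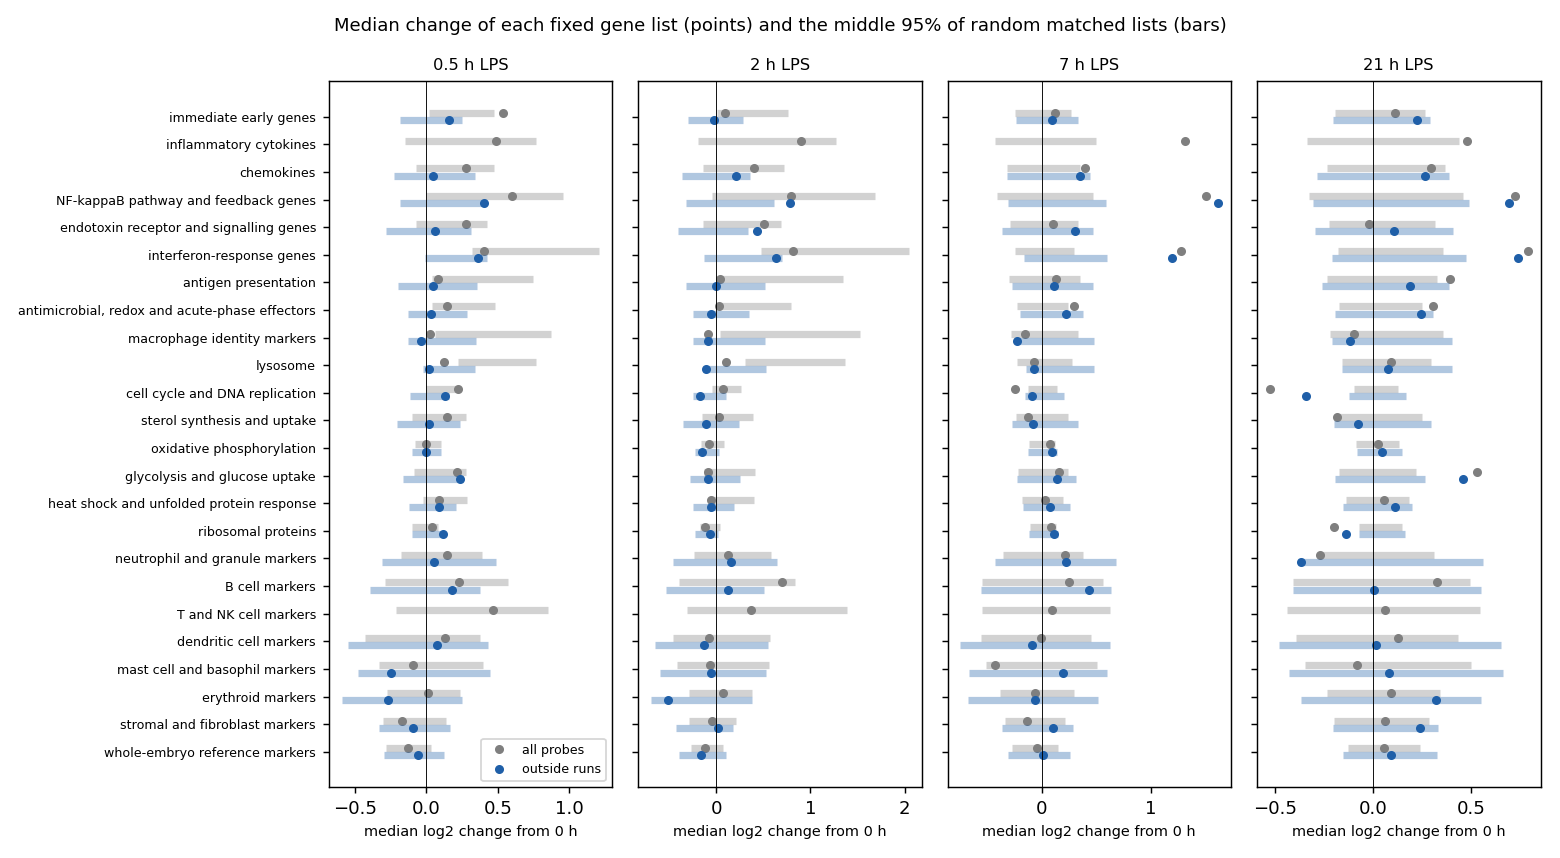
Median log2 change from 0 h (horizontal axis) of each of the 24 fixed gene lists (vertical axis) at each time of LPS, with all probes (grey points) and without the affected runs (blue points); bars are the middle 95% of random matched lists. At 7 h and 21 h the NF-kappaB and interferon-response points lie to the right of their bars under both choices, and at 21 h the cell cycle points lie to the left; under quantile normalization the interferon-response median is below 0 at 0.5 h and 2 h.

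Lists that lay outside the middle 95% mainly at 0.5 h or 2 h, or not at all, follow. Oxidative phosphorylation genes had medians of 0.072 and 0.028 at 7 h and 21 h, heat shock genes 0.033 and 0.059, and lysosome genes -0.073 and 0.094. At 0.5 h and 2 h the lysosome medians of 0.12 and 0.10 lay at percentiles 0.210 and 0.060, where the middle 95% of random lists ran from 0.22 to 0.77 and from 0.30 to 1.36. As for the other early calls with all probes, these random lists were matched on a mean that includes high early values of the runs. Without the runs the lysosome medians lay at percentiles 5.63 and 4.32. Under quantile normalization they were -0.81 and -0.79, or -0.25 and -0.41 over the probes outside the runs. Macrophage identity markers had medians of 0.025 and -0.081 at 0.5 h and 2 h (percentiles 1.13 and 0.390; -1.90 and -1.71 under quantile normalization, but -0.10 and -0.74 when that used only probes outside the runs) and of -0.16 and -0.094 at 7 h and 21 h. Without the runs the 7 h median was -0.22 at percentile 2.04. Under quantile normalization of the probes outside the runs the late medians were -0.83 and -0.47, at percentiles 0.010 and 0.685. Antigen presentation genes at 2 h had a median of 0.042 at percentile 2.48 (45.4 without the runs), and the cell cycle list at 0.5 h 0.22 at percentile 98.8 (93.9 without them, and -0.10 under quantile normalization). Ribosomal protein genes had a median of 0.12 at percentile 99.3 at 0.5 h without the runs, against 86.1 with all probes. Markers of other cells had medians at 7 h and 21 h of 0.25 and 0.33 for B cells, 0.095 and 0.064 for T and NK cells, -0.0066 and 0.13 for dendritic cells, and -0.43 and -0.079 for mast cells. Single members stood apart from these medians. The B cell gene Cd79b was 4.13-fold, 5.30-fold and 3.46-fold higher at 2, 7 and 21 h on a probe outside the runs, and Vpreb1 2.05-fold at 7 h, where the mast cell genes Mcpt4 (-1.92) and Cpa3 (-1.05) lay lower. For erythroid cells the medians were -0.060 and 0.095, for stroma -0.14 and 0.061, and for whole embryo -0.039 and 0.056. Over the 96 combinations of list and time, 13 lay high and 10 low, where 4.8 of random lists would. Without the runs it was 8 and 3 of 88, where 4.4 would. Genes of a list are not independent and the times share the 0 h array, so these excesses are no test.

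By correlation, the changes at 7 h and 21 h resembled each other most closely. Of the genes at least 2-fold higher, 151 were shared between these times. Independent lists of 352 and 263 genes would share 10.7, and the top genes of simulated unchanged arrays with the same 0 h array, in lists of these sizes, shared 65. At the 2-fold limit itself the simulated arrays shared 14. Of the lower genes 50 were shared, against 3.95 and a simulated 32. Without the affected runs 88 higher and 32 lower genes were shared, against 6.92 and 1.86 for independent lists and a simulated 42 and 18. The overlap of lower genes does not single out this pair: without the runs, 0.5 h with 7 h shared 32 (1.69 and a simulated 18) and 2 h with 7 h 35 (2.67 and 22). Nor does that of higher genes, as 0.5 h with 2 h shared 437 (63.7 and a simulated 232), and 44 without the runs (3.25 and 24). Part of each overlap may come from the shared 0 h array. Shared genes include Il1a, Cxcl10, Cfb, Rsad2, Ifit1, Fgl2 and Irf7 on the higher side and Ccnd1 and Myh11 on the lower. Across genes, which are not independent replicates, Pearson's r was 0.688 and Spearman's rho 0.633, where unchanged arrays sharing the 0 h array gave r = 0.50. The covariance was 0.19 against 0.089 in the simulation. With no shared array r was 0.313, which a batch difference between early and late arrays could also give. For 0.5 h and 2 h r was 0.658 with all probes but 0.371 without the affected runs, below the simulated 0.486. Their covariance exceeded the simulated one by 0.34 with all probes, more than the 0.10 of 7 h and 21 h, but without the runs by 0.012 against 0.088. For 0.5 h with 7 h and with 21 h r was 0.169 and 0.201, and for 2 h with 7 h and with 21 h it was 0.0984 and 0.157. All 4 lie below the simulated values of 0.49 to 0.50. Without the runs the covariance of 2 h with 7 h was 0.12 against a simulated 0.078, and that of 2 h with 21 h 0.088 against 0.079, although r was lower than simulated.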

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

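The probes that no gene name covers were not used in the comparisons. Among the 2141 of them measured on all 5 arrays and lying outside the affected runs, 114 were at least 2-fold above 0 h at 7 h and 64 lower. At 0.5, 2 and 21 h, 50, 94 and 81 were higher. The share of 5.32% at 7 h stands beside 5.04% of all probes outside the runs.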

How the results depend on the processing

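Leaving out the affected runs, its 5% limit, quantile normalization without the runs, and reading the values as log2 were chosen after seeing the data; the other settings were fixed before. No paired analysis was possible because each time has 1 array and no result comes from a test. The cause of a move was not tested unless given. Genes at or beyond 2-fold numbered 601, 1166, 625 and 388 at 0.5, 2, 7 and 21 h. By construction other limits move these counts: 1476, 2380, 1930 and 1348 at 1.5-fold, 282, 621, 147 and 97 at 3-fold, 1041, 1911, 1222 and 809 with single probes counted, and 58, 175, 12 and 10 with values read as log2. Without the affected runs they were 136, 346 and 218 at 0.5, 2 and 21 h (443 at 7 h, within 1.5 times), and at the 5% limit 53, 146, 211 and 121, with 5996 and 3636 genes left. Against the 0.5 h array they were 944 at 7 h and 822 at 21 h, and under quantile normalization 715 at 21 h. The share of higher genes among them, 85.5%, 91.9%, 56.3% and 67.8%, was 44.6%, 52.1%, 44.7% and 45.3% under quantile normalization and, without centring, 30.1% at 7 h and 46.1% at 21 h. Against the 0.5 h array it was 24.9% at 7 h and 23.7% at 21 h, and against the mean of both baselines 37.1% and 33.1%. Without centring the median gene shifted by 0.10, -0.22 and -0.12 at 2, 7 and 21 h. The other counts stayed within 1.5 times. Signal over background was not analysed here, so which ratios rest on dim spots is unknown.

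Under quantile normalization the list medians of interferon-response genes were -0.58 and -0.63 at 0.5 and 2 h, of macrophage markers -1.90 and -1.71, and of lysosome genes -0.81 and -0.79. They were -0.31 for antigen presentation at 2 h and -0.096 for the cell cycle at 0.5 h. Probes of the affected runs took 86.9% and 90.3% of the highest 5% of ranks at 0.5 and 2 h, against 58.3% at 0 h, so this scaling can push down genes that rank high at 0 h. Over the probes outside the runs it gave interferon-response medians of 0.031 and 0.13, macrophage medians of -0.10, -0.74 and -0.83 at 0.5, 2 and 7 h, lysosome medians of -0.25 and -0.41, -0.13 for antigen presentation at 2 h and 0.20 for mast cells at 7 h. The macrophage median at 0.5 h was -0.022 without centring, -0.036 with the probe of largest mean value and -0.038 without the runs, and its mean at 2 h was 0.30. The lysosome median at 2 h was -0.060 against 0.5 h and -0.11 without the runs, and the mast cell median at 7 h 0.20 without the runs. Means in place of medians gave 1.88 and 1.62 for cytokines at 7 and 21 h and 1.10 for effectors at 21 h. Against 0.5 h the NF-kappaB medians were 0.86 at 7 h and 0.12 at 21 h, and the B cell medians -0.49, -0.61 and -0.50 at 2, 7 and 21 h. All other list medians kept their direction where called and moved by less than the spread between probes. That spread is of single genes and is a wide bound for the median of a list. It passed, for example, the interferon-response median at 2 h going from 0.82 to 0.13. Calls of lists as high or low were lost 14 times without the runs, 7 against the 0.5 h array, 6 with means, 6 with random lists not matched, 5 under quantile normalization, 5 with the filter on low ratios, 3 with the probe of largest mean value, 11 under quantile normalization without the runs and 0 without centring. Calls were gained 4, 5, 11, 12, 4, 0, 3, 7 and 0 times in the same order. Among the calls lost against 0.5 h were chemokines at 7 h and cytokines, NF-kappaB and neutrophil markers at 21 h. Quantile normalization lost chemokines at 7 h and antigen presentation and sterol synthesis at 21 h.

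The correlation of changes at 0.5 and 2 h was 0.371 without the runs. Those of 0.5 h with 7 and 21 h were 0.331 and 0.363 under quantile normalization and 0.381 and 0.333 without the runs. Those of 2 h with 7 and 21 h were 0.307 and 0.352, then 0.362 and 0.328, and -0.249 and -0.229 with no shared array, where 7 h with 21 h gave 0.313. With no shared array and without the runs they were 0.0886 and 0.0413, so the negative sign was not seen there, and 7 h with 21 h gave 0.356. The likely direction of the ratio held with erythroid or stromal in place of embryo markers.

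Of named genes at least 2-fold from 0 h, 29 values turned sign against the 0.5 h array, by construction where 0.5 h was itself far from 0 h. At 2, 7 and 21 h these were Stfa3 (0.81, 0.74, 0.71), Prl8a1 (0.40, 1.03, 0.68), Klhdc3 (0.48, 0.0037, 0.074) and Col22a1 (0.72, 0.12, 0.32). At 2 and 7 h it was Serpinf1 (0.63, 1.35), at 7 and 21 h Fcgr1 (-5.31, -5.55) and Ier3 (-0.15, -0.31), and at all 3 times Pdzph1 (-2.15, -6.94, -7.00). At 2 h they were AV064505 (-2.62), Ccdc32 (-2.03), Lama1 (-1.91) and Rcbtb2 (-0.48), at 7 h Junb (-0.73), and at 21 h Fbxo31 (-0.89), Kcne1 (-5.60) and Spock1 (0.29). Under quantile normalization 18 such values turned, most of them at 0.5 and 2 h, where the runs hold most of the top ranks. At 0.5 h these were Ifit1 (-0.11), Cdca5 (-0.038), Cyp2e1 (-0.24), Ly6g2 (-1.64), Pdxk (-1.39) and Pir (-1.01). At 2 h they were Ccdc32 (-1.36), Ccl9 (-1.10), Cyp2e1 (-0.30), Fcgr1 (-0.50), Ifi204 (-1.95), Irf7 (-1.86), Junb (-0.29), Myh11 (-2.82), Pdxk (-1.64) and Rsad2 (-0.70), and at 7 h B2m (-0.11) and Fcgr1 (-0.25). Of these, 6 could be scaled over the probes outside the runs and 0 turned: Ccdc32 (0.75), Ifi204 (0.31), Irf7 (0.033) and Pdxk (0.26) at 2 h, Pdxk at 0.5 h (0.51) and B2m at 7 h (0.29). Of the genes named up to here, none at or beyond 2-fold turned without centring or, where measured, without the runs, and smaller changes were not counted. List members not named there were not covered, and some turned, such as Arg2 at 0.5 h (1.45, but -0.21 without the runs).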

Other observations

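The genes named in the next 2 paragraphs were chosen after their values were seen. So were the tests below, except the 2 on the runs of probe numbers and the first reading of the interferon and cell cycle lists without these runs. As first written, that reading treated 2, 7 and 21 h together for interferon genes and 7 and 21 h together for cell cycle genes. Neither list met its joint condition at every time. For cell cycle genes the value named beforehand for the runs as the cause, a median at 7 h above -0.3 or inside the random range, was met (-0.094). The times were taken apart only after that.

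Some genes stood at both late times apart from both early arrays. On the 7 h and 21 h arrays, 62 genes lay at least 2-fold above the higher of the 0 h and 0.5 h values and 28 at least 2-fold below the lower one. The other ways of pairing these 4 arrays gave 0 and 5 genes (0 h with 7 h) and 3 and 3 genes (0 h with 21 h). Without the affected runs the numbers were 44 and 11, against 0 and 1 and 3 and 3. Each of the other pairings mixes early and late arrays. A batch difference between early and late arrays would therefore give the same contrast and cannot be told apart from time. Among the higher genes outside the fixed lists were Mxd1, an antagonist of Myc (6.42-fold at 7 h and 3.97-fold at 21 h), the stress-associated gene Serp1 (4.59-fold and 2.53-fold, 3 probes), the copper transporter gene Slc31a2 (2.18-fold and 2.64-fold, 3 probes), and Aoah (2.52-fold and 4.68-fold), whose enzyme removes acyl chains from LPS. Insig2, a brake on sterol synthesis, was 5.87-fold and 3.95-fold higher, while its list had medians of -0.12 and -0.18. Among the lower genes were Pole2, a DNA polymerase subunit (log2 changes -1.58 and -1.04), and Parp1 (-1.22 and -1.17). Tipin, of the replication fork (-1.12 and -1.19), and Rgs2 (-1.53 and -1.66) were lower too. The single probes of Aoah, Insig2, Pole2, Parp1 and Rgs2 lie in affected runs. Mxd1, Serp1, Slc31a2 and Tipin have probes on both sides.

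The 3 cyclin D genes did not move together. At 7 h Ccnd1 had a log2 change of -2.29 (SD over probes 0.97, 3 probes) and Ccnd2 one of 1.55 (SD 0.49, 6 probes), while at 21 h Ccnd2 stood at 0.35 and Ccnd1 at -2.06. Ccnd3, on 1 probe in an affected run, had changes of -0.21 and 0.077.

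The first pattern is the high ratios in runs of probe numbers at 0.5 h and 2 h. With runs defined on odd-numbered probes only, even-numbered probes inside them exceeded probes of the same gene outside them at 2 h by a median of 0.36 on the log2 scale (95% bootstrap interval 0.28 to 0.44, 587 genes, 67.5% of them positive). That is what extra signal in these spots, whatever gene they hold, would give. Of 108 genes whose inside probes were at least 2-fold higher, 9 (8.33%, exact 95% binomial interval 3.88% to 15.2%) had outside probes that were too, against 3.92% of all such genes, which argues against LPS having raised most of these genes. What made the signal stays open, and the 2-fold counts at 0.5 h and 2 h with all probes are likely inflated.

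The second pattern is the interferon-response genes. Without the affected runs their median was 1.19 at 7 h and 0.74 at 21 h. Against the 0.5 h array it was 0.89 and 0.39, with random lists up to 0.47 and 0.34. Neither the runs nor low readings on the 0 h array alone therefore account for all of the late values. At 21 h the value of 0.39 lies close to its limit, so low 0 h readings may account for part of the 0.74. At 2 h the median without the runs was 0.63 at percentile 95.9, which decides neither way. A response of these cells to LPS may underlie the late values, but a difference between arrays stays open: 415, 477 and 484 probes had no value on the 0, 0.5 and 2 h arrays against 158 and 179 at 7 h and 21 h, a split that falls together with time.

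The third pattern is the lower cell cycle genes. At 21 h the median without the runs was -0.34, below all random lists. High 0 h readings in these runs therefore do not account for all of the lower values. With all probes the median was -0.52, with 18 of 55 genes at least 2-fold lower, against 6 of 31 without the runs. The runs may therefore account for part of the lower values at 21 h. At 7 h the median without the runs was -0.094 at percentile 10.1, and the low median with all probes may come from the runs. In 16 genes with probes on both sides the inside probes lay lower at 7 h by a median of -0.29 (bootstrap interval -0.45 to 0.032). More signal of the embryo reference at 21 h cannot be told apart, because the embryo markers had a median of 0.092 with an interval from -0.33 to 0.36 that spans the bound of -0.17. Nor can a separate batch of late arrays, because the list stood at -0.17 at 2 h, inside its random range of -0.24 to 0.11, and time and array cannot be separated with 1 array per time.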
